A study of Mus musculus with 32 samples.

How the data were processed

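The series holds 32 ChIP-seq samples of J1 mouse ES cells. Of these, 21 are immunoprecipitations of 7 targets in wild-type, Taf5l-KO and Taf6l-KO cells, 5 are streptavidin bioChIP samples (2 TAF5L-FB lines, 2 TAF6L-FB lines and BirA), and 6 are inputs. Per the labels' protocols, antibodies were used for the 7 targets, and streptavidin beads with an SDS wash for the tagged proteins. Groups were taken from the sample labels. Replicate 1 and 2 of each tagged protein are the lines in the order in which they were listed. The labels do not say more about how far the lines are independent.

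The 26 files used are peak lists, 1 per immunoprecipitated library, so nothing was pooled. Reads were aligned with Bowtie2 2.3.2 to mm9, and deepTools 2.5.3 was used, per the submitters' processing notes. Peaks were called with MACS2 2.1.1.20160309 against an input library, with at most 1 tag kept per position, a q cutoff of 0.05 and a tag size of 50 bp, per the file headers. H3K9ac, H3K4me3 and the 3 RNA polymerase II antibodies were called with broad linking (second cutoff 0.1) and Myc, Oct4, BirA and the tagged proteins without it, per the file headers. The fragment size was modelled for each library, except for the 4 TAF lists, where it was set to 300 bp, per the file headers. The larger of the ChIP and input libraries was scaled down to the smaller one, per the file headers. The 3 wild-type, Taf5l-KO and Taf6l-KO inputs held 7771755, 6245652 and 5923469 unique tags. The knockout inputs themselves were not analysed here.

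For each peak the deposited lists give the pileup height, a signal that depends on the depth of the library. They also give the fold enrichment, a ratio of that pileup to the local background that the authors' peak caller estimated from the input, and −log10 p and −log10 q, as deposited. These are the authors' values per peak and were used only to rank, filter or describe peaks within a list. They were not used to compare signal between genotypes. Values of different libraries were set side by side only in matching peaks of 2 antibodies on −log10 q and in averaging the fold enrichment of a TAF region over its lines.

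Peaks on chromosomes 1 to 19, X and Y were kept. Mitochondrial and unplaced contigs were set aside. A peak counted as kept, or shared, when at least 1 bp overlapped. Loss means that no knockout peak overlapped a wild-type peak. For TAF5L-FB and TAF6L-FB, the regions of both lines were joined and those overlapping a BirA peak removed. Background for region overlaps came from 1000 circular shifts of the TAF regions along each chromosome. Loss at TAF-bound peaks was set against 10000 random sets of unbound wild-type peaks with as many from each of 10 strata of wild-type fold enrichment, and described by its place among them. Joint loss in both knockouts was set against 10000 shuffles within the same strata. There is 1 library per antibody and genotype, so no significance test between genotypes was made and no p-value was computed. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, and neighbouring peaks are not independent.

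The overlap and resampling steps were tested on simulated lists. A simulated list made from the wild-type Oct4 peaks with 41.2% of the 2564 peaks retained gave 41.2%. Loss simulated to depend on the stratum of strength alone gave a difference of −0.179 percentage points at 308 bound Oct4 peaks. A simulated excess of 29.0 points came back as 32.6. Joint loss simulated as independent gave a ratio of 1.00 to the shuffles. Simulated loss did not vary with strength inside a stratum, so strength differences left there were not checked.

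Regions named in the text follow a rule fixed before the data were examined. Per antibody these are the 3 wild-type peaks with the highest fold enrichment that no knockout peak overlapped, the 3 that peaks of both knockouts overlapped, and the 2 strongest peaks of each knockout that no wild-type peak overlapped. For the tagged proteins they are the 5 regions with the highest mean fold enrichment among those found in both lines and outside BirA regions. The text gives part of these for Myc, H3K9ac, H3K4me3 and RNA polymerase II. The run of peaks on chromosome 3 as a whole was singled out after its values were seen. The run of TAF6L-FB line 2 peaks on chromosome 9 was also named outside this rule. Gene lists had also been fixed, but the gene table used names positions of another genome build, GRCm38, so no peak was assigned to a gene, and the state of the targeted genes themselves was not analysed here.

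Alternatives chosen before the data were examined were a stricter threshold (−log10 q of at least 5), the strongest 1000 wild-type peaks, 50% coverage, a window of 1000 bp, removal of chromosome Y and BirA regions, merging of peaks less than 1000 bp apart, leaving out each tagged line, only regions found in both lines, BirA regions kept, and matching on peak width. Added after the data were seen were the removal of the run on chromosome 3 with the region on chromosome X, matching on H3K4me3 overlap as well as strength, and joint loss among wild-type peaks with −log10 q of at least 5. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.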

Results

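Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in J1 mouse embryonic stem (ES) cells to compare wild-type cells with cells lacking Taf5l or Taf6l. TAF5L and TAF6L are relatives of TAF5 and TAF6 and belong to SAGA-type coactivator complexes, which carry a histone acetyltransferase that acts on lysines of histone H3. Immunoprecipitations of 7 targets were each made in 3 genotypes, with 1 library per antibody and genotype. The targets were the transcription factors Myc and Oct4, the histone marks H3K9ac and H3K4me3, and RNA polymerase II in its total form (RNAP) and with phosphorylated serine 5 (RNAP-ser5) or serine 2 (RNAP-ser2) in its C-terminal repeats. In addition, TAF5L and TAF6L carrying a Flag-Biotin tag (FB) were pulled down with streptavidin, a procedure called bioChIP, from 2 cell lines per protein, and cells with the biotin ligase BirA served as the control. The 21 libraries of the knockout series held between 1702363 and 22968606 unique tags. The 5 bioChIP libraries held between 18292747 and 27775010. The shallowest library was RNAP-ser5 in Taf6l-KO, in which 92.6% of the tags were duplicates. Without replicates of the knockout series, no test between genotypes was possible, and the exact (Clopper-Pearson) 95% binomial intervals given with shares cover counting error only. All positions are in the mouse genome build mm9, and no gene names were attached to them because no annotation of that build was used.

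The first question was whether histone acetylation was altered in the knockout cells. The H3K9ac list shrank from 4131 peaks in wild-type cells to 110 in Taf5l-KO and 898 in Taf6l-KO. A Taf5l-KO peak overlapped 105 wild-type H3K9ac peaks, a share of 2.54% (95% interval 2.08 to 3.07), and a Taf6l-KO peak overlapped 792, a share of 19.2% (18.0 to 20.4). These shares depended on the setting, at 0.508% and 7.36% with 50% of the wild-type peak covered and 8.5% and 46.0% for the strongest 1000 wild-type peaks. The ratios of peak number, 0.0266 and 0.217, were 0.0471 and 0.356 at −log10 q of at least 5. The covered sequence fell from 2.59 Mb to 0.0251 Mb and 0.330 Mb. The knockout ChIP libraries held 1.32 and 1.07 times the unique tags of the wild-type library, but all were scaled down to their inputs, which held 0.804 and 0.762 times the unique tags of the wild-type input. Few listed H3K9ac peaks were specific to the knockouts, since 95.5% (89.7 to 98.5) of the Taf5l-KO peaks and 89.8% (87.6 to 91.7) of the Taf6l-KO peaks lay in the wild-type list. Lists this short cannot show whether acetylation specific to the knockouts was rare.

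The wild-type H3K9ac peaks that were listed in neither knockout numbered 3333. These places otherwise looked like active promoters in all 3 genotypes. Of the 3333, 98.3% overlapped an H3K4me3 peak in wild-type cells, 96.9% in Taf5l-KO and 97.1% in Taf6l-KO. RNAP peaks covered 88.6% of them in wild-type cells, 93.5% (92.6 to 94.3) in Taf5l-KO and 93.8% (92.9 to 94.6) in Taf6l-KO. The strongest of these peaks lay on chromosome 10 from 126748139 to 126748743, with a fold enrichment of 12.1, and also carried Myc, H3K4me3 and all 3 forms of RNA polymerase II in wild-type cells. The next lay on chromosome 12 from 8647640 to 8647857 (10.7) and on chromosome 4 from 133523507 to 133523827 (9.81), the latter overlapping a TAF6L-FB region. Peaks were also kept in both knockouts, 99 in all, led by a peak on chromosome 11 from 101519316 to 101519548 (10.5) that overlapped Oct4, H3K4me3, RNA polymerase II and TAF6L-FB.

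**Figure D1:**
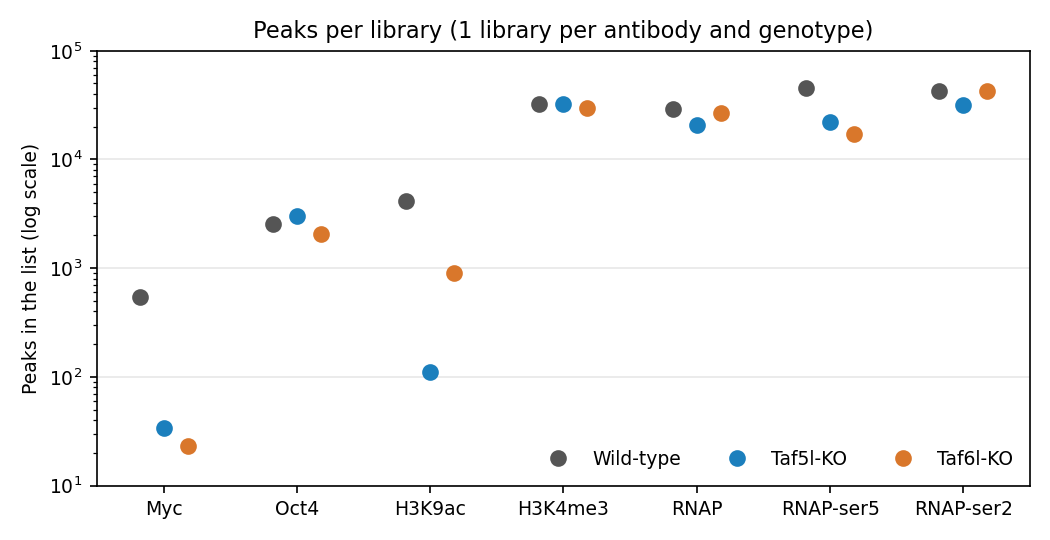
Number of peaks on the kept chromosomes (log axis) for each antibody in wild-type, Taf5l-KO and Taf6l-KO cells, 1 point per library. H3K9ac falls from 4131 to 110 and 898 peaks and Myc from 538 to 34 and 23, while H3K4me3 stays between 29463 and 32370.

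Kept shares rose with peak strength. In the weakest 10% of the wild-type H3K9ac list, 0 of 414 peaks were overlapped in Taf5l-KO (upper limit 0.887%) and 8.21% (5.75 to 11.3) in Taf6l-KO. In the strongest 10%, with fold enrichments from 6.49 to 14.9, the shares were 13.6% (10.4 to 17.2) and 62.5% (57.6 to 67.2). Taf6l-KO thus kept more H3K9ac peaks than Taf5l-KO in this pair of libraries, a difference that has no replicate check.

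Binding of Myc, a transcription factor of growth genes, was compared in the same way. The Myc list fell from 538 peaks in wild-type cells to 34 in Taf5l-KO and 23 in Taf6l-KO. Only 21 wild-type peaks, or 3.90% (2.43 to 5.90), were overlapped in Taf5l-KO and 9, or 1.67% (0.768 to 3.15), in Taf6l-KO. These shares were 2.22% and 0.494% at −log10 q of at least 5, and 1.12% and 0.186% with 50% of the wild-type peak covered. Even in the strongest 10% of the wild-type list the shares were 15.1% (6.75 to 27.6) and 3.77% (0.460 to 13.0). Unique tags in the knockout libraries were 1.2 and 0.909 times those of the wild type. The fragment size that the peak caller modelled was 95 bp for the wild-type library and 51 and 50 bp for the knockouts, near the tag size of 50 bp.

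The wild-type Myc peaks lay at promoter-like chromatin. Of the 538, 83.6% (80.2 to 86.7) overlapped H3K4me3 and 86.1% (82.8 to 88.9) overlapped RNAP in wild-type cells. The same places still carried H3K4me3 in 82.3% (78.9 to 85.5) and 83.6% (80.2 to 86.7) and RNAP in 87.0% and 87.0% of cases in Taf5l-KO and Taf6l-KO. Their overlap with H3K9ac went from 59.7% (55.4 to 63.8) to 3.53% (2.14 to 5.46) and 23.0% (19.6 to 26.8). The strongest Myc peaks found in wild-type cells only were on chromosome 4 from 46463508 to 46463900 (fold enrichment 34.5), chromosome 4 from 117508998 to 117509280 (29.3) and chromosome 8 from 72682482 to 72682850 (28.9), each at wild-type H3K9ac, H3K4me3 and RNAP peaks. Both knockouts kept 4 wild-type peaks. The strongest was on chromosome 1 from 135027571 to 135028015 (23.0) and overlapped a TAF6L-FB region. The next were on chromosome X from 103382070 to 103382315 (9.88) and on chromosome 11 from 57916185 to 57916401 (9.31). Whether the overlap on chromosome X reflects kept Myc binding is uncertain, as described below.

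Most Myc peaks that were new in the knockouts came from 1 place. A run of short peaks on chromosome 3 between 123072243 and 123088806 held 12 of the 34 Taf5l-KO peaks and 11 of the 23 Taf6l-KO peaks, and none of the wild-type Myc peaks. They included the strongest knockout-specific Myc peaks, from 123083138 to 123083228 in Taf5l-KO (fold enrichment 16.4) and from 123077661 to 123077806 in Taf6l-KO (33.2). The wild-type Oct4 list held 11 peaks at the same pieces, with fold enrichments from 22.8 to 74.4. The Oct4 lists of Taf5l-KO and Taf6l-KO held 1 and 0 there. The region on chromosome X named above, from 103382001 to 103382636, had a fold enrichment of 87.4 in wild-type Oct4. For Myc it reached 12.6 in Taf5l-KO and 33.2 in Taf6l-KO, while it was in neither Oct4 knockout list. It was also listed for H3K4me3 and RNAP in all 3 genotypes. Unlike the run, it was listed in wild-type cells for Myc (9.88), RNAP and RNAP-ser2. An H3K4me3 peak overlapped 1 piece of the run in wild-type, Taf5l-KO and Taf6l-KO cells (10.5, 13.3 and 11.5). So did an RNAP peak in Taf5l-KO (5.26) and Taf6l-KO (4.23). Without both places, chosen after the data were seen, 20 Taf5l-KO and 11 Taf6l-KO Myc peaks were left, and the ratios to wild type fell to 0.0372 and 0.0205.

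**Figure D2:**
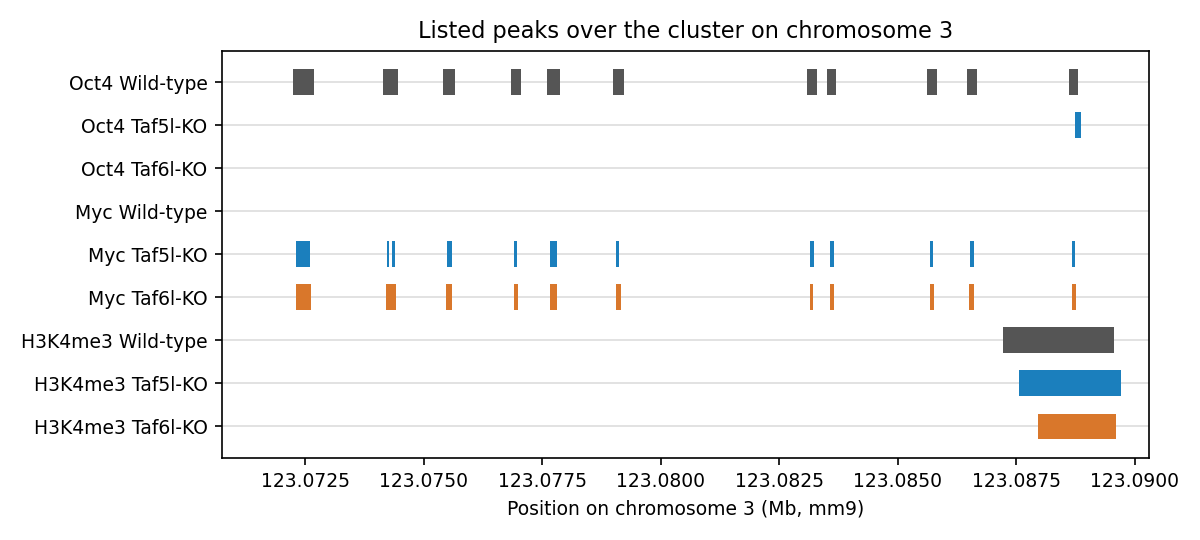
Positions of listed peaks (mm9, Mb) over the run of short peaks on chromosome 3, 1 row per library and 1 bar per peak, coloured by genotype. The 11 pieces recur in wild-type Oct4 and in both Myc knockout libraries, and the H3K4me3 peak at the right end is present in all 3 genotypes.

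Oct4, the POU-family factor of pluripotent cells, kept a large part of its sites. Its list held 2564 peaks in wild-type cells, 3034 in Taf5l-KO and 2049 in Taf6l-KO, ratios of 1.18 and 0.799. Of the wild-type peaks, 59.1% (57.2 to 61.0) were overlapped in Taf5l-KO and 46.5% (44.6 to 48.5) in Taf6l-KO. In the strongest 10% these shares were 89.8% (85.5 to 93.3) and 87.1% (82.4 to 91.0). Oct4 sites were mostly away from promoter-like chromatin, as 13.2% (11.9 to 14.6) overlapped H3K4me3 and 1.48% (1.05 to 2.03) overlapped H3K9ac in wild-type cells. The strongest peaks shared by all 3 genotypes lay on chromosome 3 from 121848313 to 121848797 (87.9), chromosome 17 from 35640871 to 35641114 (36.5) and chromosome 5 from 28536452 to 28536729 (33.9). The one on chromosome 17 was bound by both TAF5L-FB and TAF6L-FB. The strongest peaks found in wild-type cells only were the region on chromosome X and 2 pieces of the run on chromosome 3, from 123072243 to 123072671 (74.4) and from 123075410 to 123075651 (53.4). Together these 2 places made up 9 of the 10 strongest wild-type Oct4 peaks.

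Peaks of Oct4 outside the wild-type list numbered 1520 in Taf5l-KO and 855 in Taf6l-KO. Of these, 23.2% (21.1 to 25.4) and 41.4% (38.1 to 44.8) overlapped a peak of the other knockout. The strongest were on chromosome 2 from 26298451 to 26298698 (24.6) and from 127431048 to 127431288 (22.7) in Taf5l-KO, and on chromosome 1 from 184121346 to 184121612 (21.4) and chromosome 17 from 15345120 to 15345352 (20.8) in Taf6l-KO.

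H3K4me3, the mark of active promoters, was the target whose peaks were kept most often. The lists held 32370 peaks in wild-type cells, 32098 in Taf5l-KO and 29463 in Taf6l-KO. A knockout peak overlapped 84.6% (84.2 to 85.0) and 80.8% (80.4 to 81.2) of the wild-type peaks. In the strongest 10% all 3237 wild-type peaks were overlapped in both knockouts, and in the weakest 10% 40.5% (38.8 to 42.2) and 31.0% (29.5 to 32.7). The strongest shared peaks lay on chromosome 11 from 61667457 to 61669063 (19.5), chromosome 1 from 172814169 to 172815861 (18.5) and chromosome 11 from 60229677 to 60232634 (18.1), each also with H3K9ac and RNAP in wild-type cells. Peaks found in wild-type cells only were weaker, the strongest being on chromosome X from 28146172 to 28146401 (7.38). One region on chromosome 18 led both lists of knockout-specific peaks, from 37778185 to 37779251 in Taf5l-KO (11.1) and from 37778083 to 37779358 in Taf6l-KO (11.7). The peak numbers themselves did not differ in a stable direction. With only peaks of −log10 q of at least 5, the ratios to wild type were 1.15 and 1.05, against 0.992 and 0.910 for the whole lists.

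**Figure D3:**
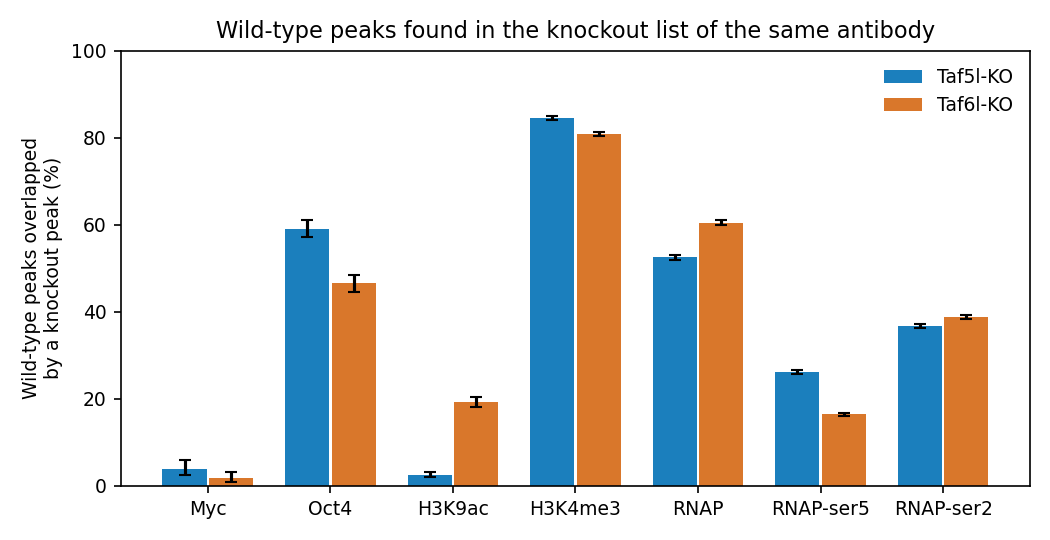
Share of wild-type peaks (percent) overlapped by at least 1 bp of a knockout peak of the same antibody, for Taf5l-KO and Taf6l-KO. Bars are 1 comparison of 2 libraries each and error bars are exact 95% binomial intervals; H3K4me3 is at 84.6% and 80.8%, and Myc at 3.90% and 1.67%.

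RNA polymerase II was compared in its 3 forms. Of the wild-type RNAP peaks, 52.5% (51.9 to 53.1) were overlapped in Taf5l-KO and 60.4% (59.9 to 61.0) in Taf6l-KO, but 96.2% (95.4 to 96.8) and 98.3% (97.8 to 98.7) in the strongest 10%. For RNAP-ser2 the shares were 36.6% (36.2 to 37.1) and 38.7% (38.2 to 39.2), and 72.2% and 75.8% in the strongest 10%. For RNAP-ser5 they were 26.2% (25.8 to 26.6) and 16.5% (16.1 to 16.8), and only 55.1% and 43.8% in the strongest 10%. With −log10 q of at least 5 in both lists, the RNAP-ser5 shares were 55.4% and 33.1% and those of RNAP-ser2 36.0% and 57.2%. The strongest peaks kept in both knockouts included chromosome 3 from 96292266 to 96293194 (fold enrichment 47.2 for RNAP), chromosome 11 from 101519380 to 101520231 (48.0 for RNAP-ser5) and chromosome 11 from 87275502 to 87276194 (42.5 for RNAP-ser2). These 3 overlapped TAF6L-FB regions. The next RNAP peaks kept, on chromosome 18 from 14806200 to 14806524 (44.7) and chromosome 19 from 18807168 to 18807467 (39.5), did not. A site on chromosome 6 from 75181718 to 75181908 led the wild-type-only peaks of RNAP (10.1) and, from 75181720 to 75181890, those of RNAP-ser5 (9.31). Peaks new in the knockouts were led by chromosome 8 from 126530292 to 126531648 for RNAP in Taf5l-KO (10.5), and by the overlapping peak from 126529898 to 126531684 for RNAP-ser2 in the same cells (10.4).

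The number of RNA polymerase II peaks depended on the peak threshold. For the whole lists, the ratios of Taf5l-KO and Taf6l-KO to wild type were 0.701 and 0.910 for RNAP, 0.489 and 0.375 for RNAP-ser5, and 0.734 and 0.986 for RNAP-ser2. With only peaks of −log10 q of at least 5, the RNAP-ser5 ratios were 1.83 and 3.16, the RNAP ratio in Taf6l-KO was 1.35 and the RNAP-ser2 ratio in Taf6l-KO was 2.67. No direction of peak number is therefore given for these. The Taf5l-KO ratios of RNAP (0.899) and RNAP-ser2 (0.726) stayed below 1 at that threshold, and with peaks less than 1000 bp apart merged (0.708 and 0.772). Unique ChIP tags also differed, at 3.07 and 1.40 times the wild type for RNAP and 2.27 and 0.440 times for RNAP-ser5. For RNAP-ser2 they were 0.856 and 0.610 times. Not all of this reached the peak calls. The RNAP knockout libraries were scaled down to inputs of 6245652 and 5923469 tags, against 5174150 ChIP tags in the wild type. RNAP-ser5 in Taf5l-KO was scaled down to 6245652 input tags, against 3871824 ChIP tags in the wild type.

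**Figure D4:**
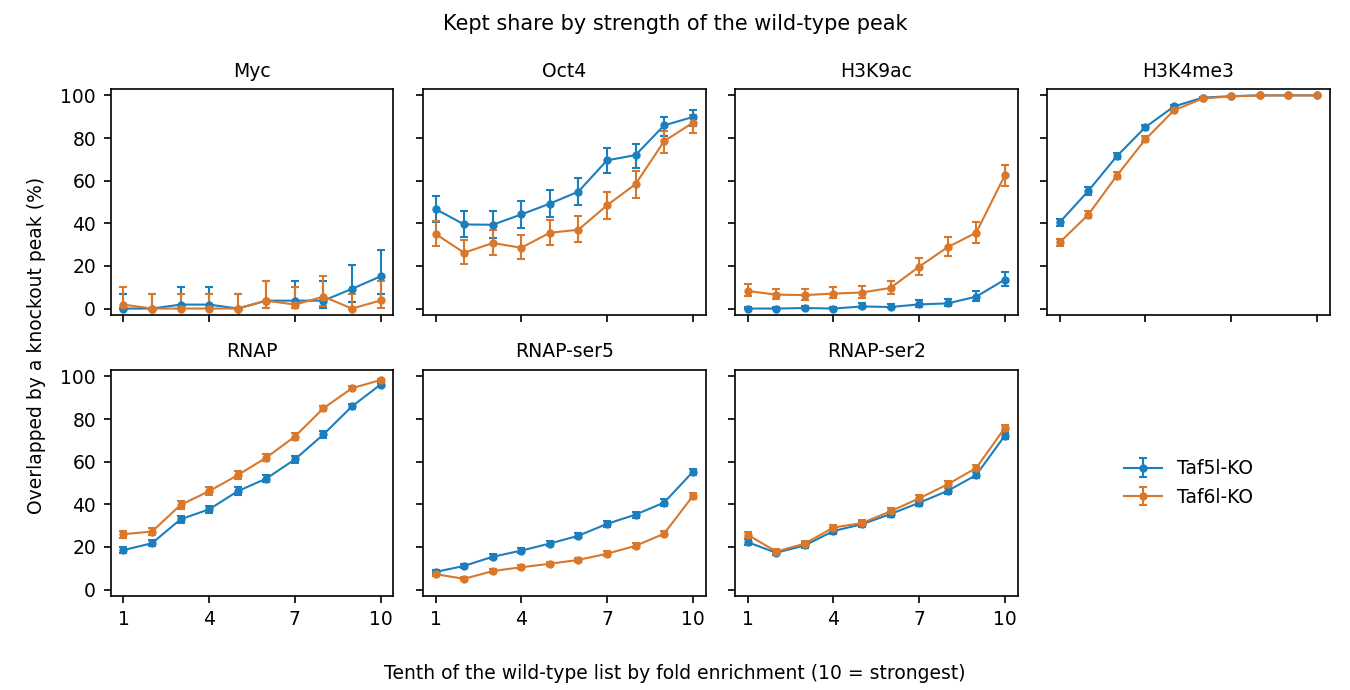
Share of wild-type peaks overlapped in each knockout (percent, with exact 95% binomial intervals) for 10 equal parts of each wild-type list by fold enrichment, 10 being the strongest. H3K4me3 reaches 100% in the strongest 10%, whereas H3K9ac reaches 13.6% in Taf5l-KO and 62.5% in Taf6l-KO and Myc 15.1% and 3.77%.

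Whether the same sites were missing in both knockouts was examined next. Of the wild-type peaks, 853 for Oct4, 3996 for H3K4me3, 10331 for RNAP and 22167 for RNAP-ser2 were overlapped in neither knockout. These were 1.31, 1.54, 1.40 and 1.24 times the means of 10000 shuffles within 10 strata of fold enrichment (652, 2598, 7357 and 17902), and above the highest shuffle for each. Among wild-type peaks with −log10 q of at least 5, a setting chosen after the data were seen, the ratios were 1.40, 27.0, 4.6 and 3.92. Fewer peaks were lost there than in the whole lists, so these ratios rest on smaller counts. For RNAP-ser5, 30752 peaks against a mean of 28646 (highest shuffle 28780) were lost in both, a ratio of 1.07 that was 2.39 among those stronger peaks. For Myc (512 against a mean of 509, highest shuffle 512), only 4 peaks were kept in both knockouts, which leaves little room for a difference. For H3K9ac, 3333 against a mean of 3282 lay above the highest shuffle of 3299. That ratio was 1.02, and 1.11 among wild-type peaks with −log10 q of at least 5. The joint loss could hardly be larger, since 3339 peaks were lost in Taf6l-KO. Of the 105 wild-type H3K9ac peaks kept in Taf5l-KO, 99 were also kept in Taf6l-KO. Both knockouts were set against the same wild-type list, so part of the excess may come from chance calls in that list. Differences in strength left within a stratum could also make losses coincide. Neither was tested.

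Peaks of the tagged proteins were then placed on these maps. TAF6L-FB gave 1140 and 628 peaks in its lines and TAF5L-FB gave 136 and 7, against 24 peaks for BirA. The BirA list was called with a modelled fragment size of 49 bp and the TAF lists with a set size of 300 bp, so the control was not called in the same way. Line 2 of TAF6L-FB shared 133 of its 628 peaks, or 21.2%, with line 1. Joined over lines and without BirA regions, there were 1625 TAF6L-FB regions and 136 TAF5L-FB regions, 133 of the latter from line 1. Of the TAF5L-FB regions, 81 of 136, or 59.6% (50.8 to 67.9), overlapped a TAF6L-FB region, against a mean of 0.0603% and at most 1.47% in 1000 circular shifts. This share was 0% without TAF5L-FB line 1, 36.8% without TAF6L-FB line 1, 41.2% without TAF6L-FB line 2 and 18.4% for TAF6L-FB regions found in both lines. In the other direction, 4.92% (3.92 to 6.09) of the TAF6L-FB regions overlapped a TAF5L-FB region. The shifts moved regions along whole chromosomes. They cannot tell whether the proteins shared places beyond both lying at promoter-like chromatin or polymerase sites.

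TAF6L-FB regions were often found at promoter-like chromatin and polymerase sites. H3K4me3 peaks of wild-type cells overlapped 58.3% of them (66.0% and 42.7% in lines 1 and 2), RNAP 54.9% (59.8% and 48.8%), RNAP-ser2 33.7% (36.6% and 29.1%), RNAP-ser5 24.0% (25.0% and 21.9%), Oct4 15.5% (14.4% and 22.2%), H3K9ac 15.1% (17.0% and 11.4%) and Myc 3.63% (4.15% and 2.74%). The highest shares among 1000 shifts lay between 0.185% for Myc and 3.75% for H3K4me3. Restricted to the 127 regions found in both lines, the share at Oct4 peaks was 39.4%. With 50% of the TAF6L-FB region covered, the shares were 5.72% for Oct4, 7.51% for H3K9ac and 1.23% for Myc. TAF5L-FB regions overlapped RNAP peaks in 64.7% (56.1 to 72.7), H3K4me3 in 39.0% (30.7 to 47.7), Oct4 in 35.3% (27.3 to 43.9), RNAP-ser2 in 33.1% (25.3 to 41.7), RNAP-ser5 in 25.0% (18.0 to 33.1), H3K9ac in 10.3% (5.74 to 16.7) and Myc in 4.41% (1.64 to 9.36), with at most 8.09% in the shifts. The TAF5L-FB shares rest on line 1. Line 2 had 3 regions outside BirA regions, of which 1 overlapped RNAP and 0 overlapped Myc, Oct4, H3K9ac or H3K4me3. Stricter lists (−log10 q of at least 5 in both) lowered the RNAP share to 20.7% for TAF5L-FB and 27.2% for TAF6L-FB, and the H3K4me3 share to 21.8% and 42.7%. The RNAP-ser5 shares fell further, to 2.3% and 6.83%, as did those of RNAP-ser2 (4.6% and 10.5%) and H3K9ac (2.3% and 6.42%). The wild-type lists were also cut at this threshold, and no shifts were run for it. These falls therefore do not show a weaker association at strong peaks.

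The strongest TAF6L-FB regions found in both lines lay on chromosome 7 from 3201083 to 3201777, with a mean fold enrichment of 7.37 (n = 2 lines), on chromosome 1 from 88383892 to 88384439 (7.03), on chromosome 12 from 87842523 to 87843261 (6.56), on chromosome 3 from 96292306 to 96293001 (6.18) and on chromosome 4 from 57703554 to 57704087 (6.17). The regions on chromosomes 7, 12, 3 and 4 overlapped wild-type Oct4 peaks, and those on chromosomes 1 and 3 overlapped H3K4me3 and H3K9ac. No TAF5L-FB region outside the BirA regions was found in both lines.

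**Figure D5:**
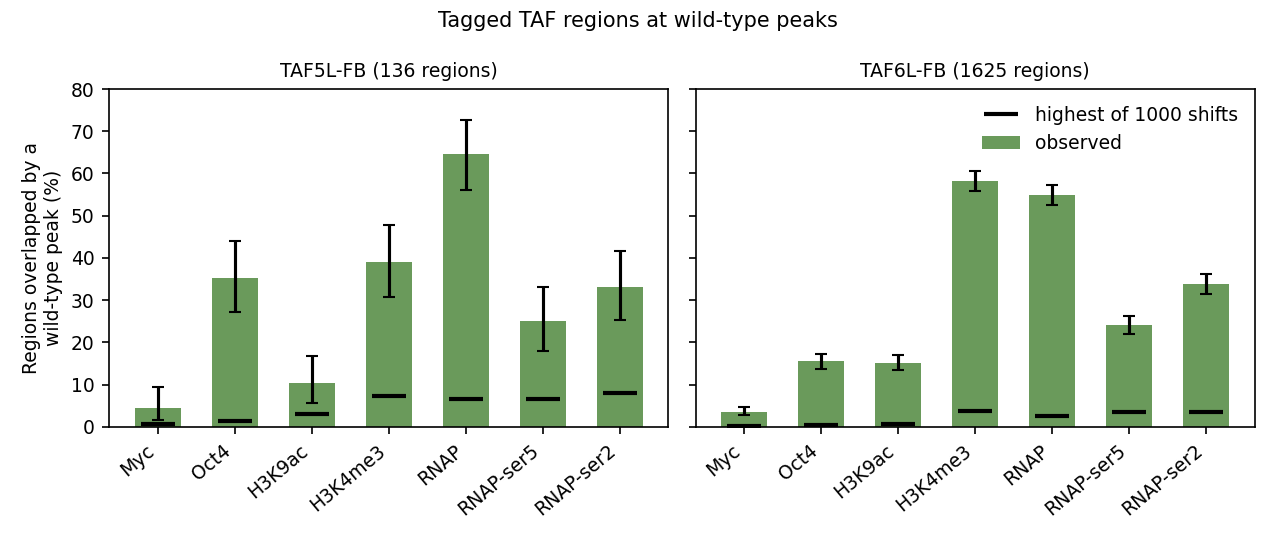
Share of TAF5L-FB (136) and TAF6L-FB (1625) regions overlapped by wild-type peaks of each antibody (percent, bars, with exact 95% binomial intervals), with the highest share among 1000 circular shifts as black lines. All 14 bars lie above their line, from 3.63% for TAF6L-FB at Myc to 64.7% for TAF5L-FB at RNAP.

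Finally, loss of peaks was compared between wild-type peaks bound by a tagged TAF and others from the same strata of fold enrichment. Strength could still differ within a stratum, as the strongest 10% spanned 7.37 to 47.2 for RNAP and 4.38 to 48.0 for RNAP-ser5. For RNAP-ser5, 78.1% and 67.7% of the strongest 1000 peaks were kept in Taf5l-KO and Taf6l-KO, against 55.1% and 43.8% of the strongest 10%. Whether bound peaks were stronger within their strata was not examined. In sets matched on strength, TAF-bound peaks were not lost more often for any of the 7 antibodies. Bound here means overlap with a joined TAF region, and most of these regions came from 1 line. Of the TAF6L-FB regions, 127 of 1625 were found in both lines, and of the TAF5L-FB regions 0 of 136. The comparison was not repeated on regions found in both lines. Among the 246 TAF-bound H3K9ac peaks, 63.4% (57.1 to 69.4) were lost in Taf6l-KO, against 73.3% on average in 10000 matched sets (central 95% from 68.7 to 77.6), and 94.3% (90.6 to 96.9) against 95.7% in Taf5l-KO (93.5 to 98.0). Among the 896 TAF-bound RNAP peaks, 7.37% and 7.03% were lost in Taf5l-KO and Taf6l-KO, against 35.9% (33.3 to 38.5) and 27.7% (25.2 to 30.1) in matched sets. For Oct4, 35.3% and 45.7% of 269 bound peaks were lost, inside the central 95% of the matched sets, which were 32.0 to 41.6 and 43.5 to 53.5. Among the 63 bound Myc peaks, 92.1% and 95.2% were lost against 96.6% and 98.8%. Of the 952 bound H3K4me3 peaks, 7.25% and 5.99% were lost against 7.83% and 9.83%. With sets matched on peak width instead, the loss of bound H3K4me3 peaks in Taf5l-KO lay 2.20 percentage points above that of the sets, and in Taf6l-KO the difference shrank to −0.798 points. The Oct4 differences also changed sign with width matching, from −1.46 to 4.07 points in Taf5l-KO and from −2.85 to 1.54 in Taf6l-KO, and were −4.25 in both knockouts when matched on strength and H3K4me3 overlap, a setting chosen after the data were seen. TAF-bound RNAP-ser2 and RNAP-ser5 peaks were also lost less often. The differences were −27.2 and −31.4 percentage points for RNAP-ser2 and −35.8 and −27.4 for RNAP-ser5 in Taf5l-KO and Taf6l-KO. With sets matched also on H3K4me3 overlap, the differences for RNAP-ser2 were −9.55 points in Taf5l-KO and −7.75 in Taf6l-KO. For RNAP-ser5 they were then −15.3 in Taf5l-KO and 1.07 in Taf6l-KO, so the lower loss of RNAP-ser5 in Taf6l-KO was not seen among peaks of the same H3K4me3 state.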

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

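All tests of explanations in this part were chosen after the results were seen. The Oct4 lists moved in opposite directions in the knockouts, with 1.18 times as many peaks as wild type in Taf5l-KO and 0.799 times as many in Taf6l-KO, and this difference was not tested, since each is 1 library. Outside the chromosomes used in the comparisons, the tagged proteins had mitochondrial peaks in numbers above the 2 of the BirA control, namely 3 in TAF5L-FB line 1, 7 in TAF5L-FB line 2 and 8 in TAF6L-FB line 2. TAF6L-FB line 1 had 1 such peak, which covered 16298 bp. On unplaced contigs, 3 peaks were listed for TAF6L-FB line 1 and 3 for line 2, against 0 for BirA.

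The near absence of H3K9ac peaks in the knockouts was weighed first. The Taf5l-KO and Taf6l-KO libraries held 1.32 and 1.07 times the unique tags of the wild-type library, which decides nothing about depth, because each library was scaled down to its smaller input. The knockout inputs were shallower, but H3K4me3 peaks with the same −log10 q as the H3K9ac peaks, called against the same inputs, were still kept at 63.4% in Taf6l-KO and 70.5% in Taf5l-KO, which argues against the inputs as the whole cause. A weaker immunoprecipitation in the knockout libraries cannot be told apart from the genotype with 1 library each, and the strongest 10% of peaks, of which 13.6% were kept in Taf5l-KO, does not decide it. The modelled fragment size was 139 bp in the wild-type H3K9ac library and 104 and 122 bp in Taf5l-KO and Taf6l-KO, and a part played by it was not tested. Lower acetylation in the knockout cells also stays open and untested.

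The loss of Myc peaks was weighed in the same way. The ChIP tag ratio of 1.2 in Taf5l-KO decides nothing here either, nor does the share of 3.77% kept among the strongest 10% of peaks in Taf6l-KO, since the inputs again set the depth. Oct4 peaks with the same −log10 q as the Myc peaks, called against the same inputs, were kept at 61.7% (lower 95% limit 59.7) in Taf5l-KO, which argues against the inputs as the whole cause there, and at 50.3% (48.4) in Taf6l-KO. The latter is far above the 1.67% of Myc peaks kept, but its limit is under the 50% set for exclusion, so a part played by the inputs stays open there. The modelled fragment size was at most 51 bp in the knockouts, near the tag size as where few sites are enriched, against 95 bp in the wild type. Neither this smaller size, as a difference in peak calling, nor a poor immunoprecipitation can be told apart from the genotype. Loss of Myc binding in the knockout cells also stays open, untested.

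The run of short peaks on chromosome 3, from 123072243 to 123088806, was weighed last. Its 11 pieces were between 188 and 429 bp long and recurred in exactly 3 lists, those of Oct4 in wild-type cells and of Myc in both knockouts. A copy of this sequence carried by the cells of 1 genotype is argued against, because the lists with the pieces came from 3 genotypes, while each of the other 23 lists held at most 1 piece. A candidate explanation is foreign DNA, such as a spliced copy of a gene, in these 3 libraries. This candidate was not tested against exons because no annotation of this build was used, and no biological explanation was tested. The region on chromosome X was in the same 3 lists, at 87.4 in wild-type Oct4 and at most 12.6 and 33.2 for Myc in Taf5l-KO and Taf6l-KO. It was also in other lists, and whether the candidate applies to it was not tested.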

How the results depend on the processing

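The removal of the run on chromosome 3 with the region on X, the matching on H3K4me3 and the joint loss at a stricter threshold were chosen after the data were seen. A share was taken as unchanged when it stayed within its 95% binomial interval or, for tagged proteins, within the SD of the 2 lines. This SD comes from the same 2 lines and was wide where they differed. At H3K4me3 it was 28.2 points for TAF5L-FB and 16.5 for TAF6L-FB. TAF6L-FB at H3K4me3 thus counted as unchanged at 42.7% and 66.0% with single lines left out. A tagged-protein share taken as unchanged is therefore no evidence of stability. H3K4me3 had the highest kept share of the 7 antibodies at each setting run. All 14 kept shares were unchanged without chromosome Y and BirA regions, and the 4 of Myc and Oct4 without the run and the region. Values in pairs are for Taf5l-KO and Taf6l-KO. Kept shares at −log10 q of at least 5 in both lists were 2.22 and 0.494% for Myc, 61.4% for Oct4 in Taf5l-KO, 3.80 and 21.3% for H3K9ac, 94.8 and 93.3% for H3K4me3, 51.9 and 81.3% for RNAP, 55.4 and 33.1% for RNAP-ser5 and 36.0 and 57.2% for RNAP-ser2. For the strongest 1000 wild-type peaks they were 79.6 and 68.6% for Oct4, 8.5 and 46.0% for H3K9ac, 100 and 100% for H3K4me3, 98.9 and 99.1% for RNAP, 78.1 and 67.7% for RNAP-ser5 and 90.6 and 93.3% for RNAP-ser2. With 50% of the wild-type peak covered they were 1.12 and 0.186% for Myc, 0.508 and 7.36% for H3K9ac, 78.9 and 74.1% for H3K4me3, 43.6 and 50.7% for RNAP, 17.8 and 10.2% for RNAP-ser5 and 25.4 and 25.7% for RNAP-ser2. Within 1000 bp they were 86.2 and 82.1% for H3K4me3, 56.9 and 66.4% for RNAP, 34.5 and 21.1% for RNAP-ser5 and 48.1 and 51.0% for RNAP-ser2.

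Ratios of peak number at −log10 q of at least 5 were 0.0471 and 0.356 for H3K9ac, 1.15 and 1.05 for H3K4me3, 1.35 for RNAP in Taf6l-KO, 1.83 and 3.16 for RNAP-ser5 and 2.67 for RNAP-ser2 in Taf6l-KO, which turned the direction except for H3K9ac. With peaks less than 1000 bp apart merged, they were 1.00 for H3K4me3 in Taf5l-KO and 1.05 for RNAP-ser2 in Taf6l-KO, again turned. Without the run and the region they were 0.0372 and 0.0205 for Myc.

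Leaving out each line in turn, the TAF5L-FB shares ranged over 0 to 4.51% for Myc, 0 to 36.1% for Oct4, 0 to 10.5% for H3K9ac, 0 to 39.8% for H3K4me3, 33.3 to 65.4% for RNAP, 24.8 to 33.3% for RNAP-ser5 and 33.1 to 33.3% for RNAP-ser2, because 1 of the lines leaves 3 regions, and the TAF6L-FB share over 14.4 to 22.2% for Oct4. TAF6L-FB regions found in both lines gave 5.51% for Myc, 39.4% for Oct4, 19.7% for H3K9ac, 68.5% for RNAP, 26.8% for RNAP-ser5 and 40.9% for RNAP-ser2; TAF5L-FB left none. With BirA regions kept, TAF5L-FB gave 31.9% for RNAP-ser2. At −log10 q of at least 5, TAF5L-FB gave 2.3% for H3K9ac, 20.7% for RNAP, 2.3% for RNAP-ser5 and 4.6% for RNAP-ser2, and TAF6L-FB 6.42% for H3K9ac, 27.2% for RNAP, 6.83% for RNAP-ser5 and 10.5% for RNAP-ser2. With 50% of the region covered, TAF5L-FB gave 24.3% for RNAP-ser2, and TAF6L-FB 1.23% for Myc, 5.72% for Oct4, 7.51% for H3K9ac, 43.4% for RNAP, 17.1% for RNAP-ser5 and 24.3% for RNAP-ser2. Within 1000 bp, TAF5L-FB gave 22.1% for H3K9ac, 33.8% for RNAP-ser5 and 41.2% for RNAP-ser2, and TAF6L-FB 5.23% for Myc, 23.7% for H3K9ac, 30.7% for RNAP-ser5 and 40.7% for RNAP-ser2. The share of TAF5L-FB regions at TAF6L-FB regions ranged from 0 to 60.9% without single lines, and was 18.4% for TAF6L-FB regions found in both lines.

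Loss at TAF-bound peaks minus that of matched sets, in percentage points, was 2.20 for H3K4me3 in Taf5l-KO and −0.798 for H3K4me3 in Taf6l-KO when matched on peak width, and −15.3 for RNAP-ser5 in Taf5l-KO, 1.07 for RNAP-ser5 in Taf6l-KO, −9.55 for RNAP-ser2 in Taf5l-KO and −7.75 for RNAP-ser2 in Taf6l-KO when matched on strength and H3K4me3. Joint loss divided by its shuffles was 27.0 for H3K4me3, 4.6 for RNAP, 2.39 for RNAP-ser5 and 3.92 for RNAP-ser2 among wild-type peaks with −log10 q of at least 5. Fewer peaks were lost there than in the whole lists. The cause of these changes was not tested. Wider promoters were not run, since no peak was assigned to a gene. No paired analysis was possible, as the knockout series has 1 library per group.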

Other observations

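The 3 tests of hypotheses in this part were written before their results were seen; the other values are described without a test. Oct4 peaks at promoter-like chromatin behaved differently from the rest. The hypothesis that Oct4 peaks overlapping H3K4me3 are kept more often than equally strong others was not borne out, and the values went the other way. In Taf5l-KO, 60.1% (95% interval 54.6 to 65.3) of the 338 Oct4 peaks at H3K4me3 were lost, against 37.8% on average in 10000 strength-matched sets of the other 2226 peaks (central 95% from 33.4 to 42.3). In Taf6l-KO, 62.1% (56.7 to 67.3) were lost against 51.2% (46.7 to 55.6). Both lay at percentile 100 of their matched sets. Each rests on 1 library per genotype and both on the same wild-type list, and no sets matched on peak width were drawn. Strength was matched by stratum only, so a difference in strength within strata was not excluded.

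A second hypothesis was that H3K9ac peaks at Myc sites are kept more often than equally strong others in Taf6l-KO. Of the 289 wild-type H3K9ac peaks that overlapped a wild-type Myc peak, 47.1% were kept, against 34.6% on average in matched sets of the other 3842 peaks (central 95% from 30.4 to 39.1), and the loss share lay at percentile 0. This is the direction of the hypothesis, in 1 library per genotype. Sets matched on peak width were not drawn, and the hypothesis was not examined in Taf5l-KO. Here too, strength was matched by stratum only. The Myc peaks themselves were nearly all missing from the Taf6l-KO list.

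The tagged proteins were compared by the marks at their joined regions, without a test of the difference. Of the TAF6L-FB regions, 52.6% (50.2 to 55.1) overlapped H3K4me3 and no Oct4 peak, and 9.85% (8.44 to 11.4) overlapped Oct4 and no H3K4me3 peak. Of the TAF5L-FB regions, nearly all from line 1, these shares were 29.4% (21.9 to 37.8) and 25.7% (18.6 to 33.9). The contrast was not stable. The TAF6L-FB lines themselves differed, with H3K4me3 at 66.0% and 42.7% and Oct4 at 14.4% and 22.2%, and the TAF6L-FB regions found in both lines overlapped Oct4 in 39.4%, above the 35.3% of TAF5L-FB. TAF6L-FB line 2 also held a run of 18 peaks at the start of chromosome 9, from 2999947 to 3038386, with fold enrichments of only 1.45 to 2.02.

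At all 4131 wild-type H3K9ac peaks, RNAP-ser2 was listed more often in both knockouts than in wild-type cells, and RNAP-ser5 more often in Taf5l-KO only. RNAP-ser2 peaks overlapped 69.2%, 74.8% and 82.9% of them in wild-type, Taf5l-KO and Taf6l-KO cells, and RNAP-ser5 peaks 50.3%, 70.7% and 47.8%. The Taf5l-KO library of RNAP-ser5 held 2.27 times the unique tags of the wild type, before it was scaled down to its input. The pattern was not a trait of the lost peaks. It was seen at the 3333 missing from both knockouts (RNAP-ser2 65.9%, 72.2% and 80.5%, RNAP-ser5 46.6%, 67.1% and 43.6%) and at the 99 kept in both (77.8%, 88.9% and 87.9%, and 63.6%, 87.9% and 58.6%). It was not seen for RNAP-ser2 at the 538 Myc peaks (74.2%, 71.2% and 73.6%), nor in Taf5l-KO at all H3K4me3 peaks (34.4% against 33.1%). For RNAP-ser5 it was seen at the Myc peaks (57.8%, 69.0% and 42.9%). H3K4me3 peaks outside the wild-type list numbered 4563 in Taf5l-KO and 3088 in Taf6l-KO, and 35.2% (33.8 to 36.6) and 52.7% (50.9 to 54.5) of them overlapped a peak of the other knockout.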
